A study of Saccharomyces cerevisiae with 7 samples.

How the data were processed

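RNA of 2 Brazilian fuel ethanol strains of Saccharomyces cerevisiae, CAT and PE-2, was compared between 2 stages of a bench-scale fermentation on 7 Agilent arrays with 2 colours. Each array held RNA of a single strain: a sample called fermentation in one dye, and in the other a sample from the bottom of the fermentor, taken after the acid treatment and before feeding. Per the labels' protocols, cells were recycled, held with sulfuric acid at pH 2.5 for 1.5 h, and fed sugar cane must with 18% sugar at 33 °C with 10% yeast (w/v). Feeding ended at 3 h and fermentation at 9 h. The labels do not say which of these times the fermentation sample is, so it is called fermentation throughout. Labelled RNA was made from 5 µg of total RNA. The labels call replicates 1 and 2 of each strain biological replicates. For each strain 3 fermentations are recorded, and the sample titles do not say which of them a replicate came from. CAT replicate 1 had 1 array with fermentation in Cy5, and each of the other 3 replicates had that array and a dye swap.

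The deposited array files hold spot intensity in both colours (mean signal, local median background and processed signal), made with Agilent Feature Extraction 9.5.3.1, per the file headers and the submitters' processing notes. The processed intensity was background-subtracted, detrended and dye-normalized by that software, per the file headers. The deposited LogRatio column is log10 of red over green processed signal, per the file headers. Other deposited columns are scores of 0 or 1 set by the software as flags for spots well above background, saturated or uneven, per the file headers. The deposited series table also holds log10 values, multiplied by 1000000000 and turned to fermentation over bottom on swapped arrays. This was found by setting each column against the same array's LogRatio, and the largest difference was 4.99e-06. No further centring was found in it. The column medians were 0 for 5 arrays, -16145318 for PE-2 replicate 2 and -62493750 for its swap. All of its columns were matched to a sample, leaving 0 unmatched.

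Log ratios were computed here with limma 3.58.1 in R 4.3.3. Mean signals were background-corrected with normexp (offset 50) and normalized within each array by loess, with control and outlier spots at weight 0; outlier spots were left out of the averages. The sign was turned on swapped arrays, the 2 spots of each gene were averaged, and arrays of the same biological replicate were averaged. This left 4 values per gene, 2 per strain. A gene was tested where its probe was well above background in at least 1 channel on at least 3 of the 7 arrays. That held for 5384 of 6256 genes, and 872 were not tested. Each gene had 1 probe sequence. Symbols came from the RefSeq table of assembly R64, in which 5756 of the 6256 systematic names were found; the other 500 kept the name in the files. The array's design was made on an older build, so no coordinates are given.

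limma's lmFit and eBayes were fitted to the strain means (2 residual and 3.53 prior degrees of freedom), with 2-sided tests and Benjamini-Hochberg adjustment over the genes tested. The comparisons were CAT against 0, PE-2 against 0, their average, and CAT minus PE-2, at an adjusted p under 0.05. Gene lists with at least 5 tested members were tested with camera, with a preset inter-gene correlation of 0.01 and with an estimated correlation, and with fry. The estimated correlation rests on the 2 residual degrees of freedom, which leaves that form of camera little power. A list that it did not call is therefore not shown to be unchanged. Its power was not simulated. The preset correlation takes the members of a list as nearly independent. Where members deviate together within a replicate, its p-values are too small. The list tests covered 38 of 39 lists, since the flocculin list had 4 tested members. VMA9 was the 1 list member not found on the array.

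The groups, tests, gene lists, rule for named genes and first set of alternatives were fixed before the data were examined. The rule named, in each strain, the 12 genes with the highest and the 12 with the lowest change among those past the threshold, changed the same way in both replicates and well above background in at least 1 channel on every array of the strain. For the strain difference, where none passed, it named the 5 genes with the lowest p in each direction, with both CAT replicates on one side of both PE-2 replicates. It added up to 4 members with the largest average change of each list described, and 12 fixed genes, of which SNO1 was not tested. The lists described were those called in either strain or in their difference, and 6 others picked after results were seen. Of 153 named genes, 12 had a probe sharing at least 20 bases with another gene's probe. Probes were not compared with other genes' transcripts, so the other probes are not shown to be specific.

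The number of arrays limits the precision. The median SE of a log2 change was 0.18 in each strain and 0.25 for the strain difference. On simulated data with 200 of 5384 genes changed (20 simulations), the fit recovered 0.6%, 30.5%, 93.5% and 98.6% of changes of 0.5, 1, 2 and 3 log2 units in 1 strain. For a strain difference of these sizes it recovered 0.3%, 3.3%, 72.9% and 92.7%. Of the calls, 4.78% were false. camera with the preset correlation found a list of 20 genes shifted by 0.5 log2 units in 20 of 20 simulations, with 1 false call in total among the 37 other lists. All simulated genes varied independently, without the deviations that genes share within a replicate of these data. The false calls are thus not error rates for these data, for genes or for lists.

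Alternatives changed the background correction, normalization, filter, value source, treatment of dyes, slide and replicate number, threshold and replicates used. A crossed pairing of replicates and centring on added control transcripts were chosen after seeing the data. The alternative of keeping a gene's brightest probe was not run, since each gene had 1 probe. limma could not estimate a slide correlation from the 4 replicate values, so that alternative was fitted to the 7 arrays.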

Results

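The study compared yeast during fermentation with yeast at the bottom of the fermentor, which had been acid-treated and not yet fed, in CAT and in PE-2. Each strain had 2 biological replicates, on 3 arrays for CAT and 4 for PE-2. Between 40.8% and 78.5% of the 6256 genes were well above background in the fermentation channel of an array, and between 74.6% and 88.2% in the bottom channel. PE-2 replicate 2 had the lowest shares in fermentation, 51.9% and 40.8% on its 2 arrays. All changes are log2 of fermentation over bottom after loess, and so are relative to genes of similar intensity on the array. They are given with the SE from limma and n = 2 biological replicates per strain unless another n is given. The median gene tested lay at -0.02 in PE-2 and moved to -0.15 under median centring. It moved to -0.25 with the scanner software's processed signals or the series table, and to -1.88 when centred on added control transcripts. The SE of a gene was the same in both strains. Swapped arrays of a replicate correlated across genes at r = 0.957, 0.953 and 0.970. Replicates correlated at 0.735 in CAT and 0.685 in PE-2, and replicates of different strains at 0.519 to 0.778; genes are not independent replicates.

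The CAT comparison asked which genes changed in that strain between the acid-treated cells and fermentation. AHP1, a thioredoxin-dependent peroxidase, rose 7.19-fold (2.85 ± 0.20, SE, n = 2), and HSP26, a small heat shock chaperone, rose 4.51-fold (2.17 ± 0.39). ADH1, the main fermentative alcohol dehydrogenase, rose 4.14-fold (2.05 ± 0.40), and TPM1, the major tropomyosin, 4.40-fold (2.14 ± 0.18). Spots of HSP26 were saturated on 3 arrays and of ADH1 on 1, so their folds are uncertain. CAT replicate 1 had no swap, so a gene's dye effect stays in its CAT value. That effect (log2 red over green) was 0.49 for HSP26, 0.29 for ADH1, 0.06 for AHP1 and -0.10 for TPM1. The CAT rises of HSP26 and ADH1 are thus likely too high. RGI2, a gene linked to respiratory growth, fell by 4.38 ± 0.31, and the mannitol dehydrogenase genes DSF1 and MAN2 fell by 3.30 ± 0.23 and 3.14 ± 0.20. Whether the probes of DSF1 and MAN2 also bind each other's transcript was not tested. The hexose transporter relatives HXT17, HXT16 and HXT15 fell by 2.74, 2.57 and 2.53 (SE 0.20, 0.20 and 0.19); the probes of HXT15 and HXT16 share at least 20 bases, so these may cross-hybridise. COX5A, a cytochrome c oxidase subunit, fell by 2.54 ± 0.17.

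Further genes that rose in CAT were PET122, a translational activator of mitochondrial COX3 (2.39), and NRK1, nicotinamide riboside kinase (2.09). BUD19 (2.31) overlaps RPL39. KTR2, a mannosyltransferase, rose by 2.03, and ECL1, RTS3, NRS1 and YDL085C-A rose by 1.94 to 2.11. SNZ3, of vitamin B6 synthesis, fell by 2.58 and may cross-hybridise with SNZ2. RPM2, the protein subunit of mitochondrial RNase P, fell by 2.66, and AGX1, alanine:glyoxylate aminotransferase, fell by 2.81. PHM6 fell by 2.84 and YNR071C by 2.68. These 24 genes had adjusted p of 0.0064 to 0.042. In all, 493 of 5384 genes passed in CAT, 213 higher and 280 lower, and 341 of them changed at least 2-fold. limma called 0 CAT genes without CAT replicate 1 (688 at an unadjusted p under 0.05), 0 without CAT replicate 2 (1223) and 0 after scale normalization between arrays (1601). With no filter on dim probes 163 genes passed, and centring on added control transcripts left 3, all lower.

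The PE-2 comparison asked the same of the other strain. AHP1 rose 19.7-fold (4.30 ± 0.20, SE, n = 2), HSP26 7.58-fold (2.92 ± 0.39) and ADH1 7.02-fold (2.81 ± 0.40). For AHP1 the log2 signal at the bottom was 8.9 in PE-2 and 11.1 in CAT, and in fermentation 13.2 and 13.9. HSP10, the mitochondrial co-chaperonin, rose 6.84-fold (2.77 ± 0.26), HXT3, a low-affinity glucose transporter, 5.48-fold (2.45 ± 0.16), and PGK1, phosphoglycerate kinase, by 2.48 ± 0.35 log2 units. RGI2 fell by 3.22 ± 0.31. SNZ3 and SNZ2 fell by 3.17 ± 0.17 and 2.92 ± 0.15. NSR1, nucleolin, fell by 2.75 ± 0.17 and ERG10, acetoacetyl-CoA thiolase of the ergosterol pathway, by 2.27 ± 0.16.

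PET122 (2.70), NRK1 (2.68), BUD19 (2.58) and SHH3 (2.52) also rose in PE-2. So did YCR013C (2.63), which overlaps PGK1, and YDR154C (2.49). RPM2 fell by 2.47, RRT13 by 2.46, DSF1 by 2.36, MAN2 by 2.33 and COX5A by 2.32. OLE1, the fatty acid desaturase, fell by 2.30 and RPS2, a ribosomal protein, by 2.20. These 24 genes had adjusted p of 0.0060 to 0.023. In all, 613 of 5384 genes passed in PE-2, 306 higher and 307 lower, and 427 changed at least 2-fold. Median centring in place of loess called 1234 (190 higher and 1044 lower), the scanner software's processed signals 1301 (490 and 811), and centring on added control transcripts 720 (1 and 719). Leaving out PE-2 replicate 1 left 46 calls, leaving out PE-2 replicate 2 left 307 and leaving out either CAT replicate left 302; without the filter 271 passed.

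**Figure D1:**
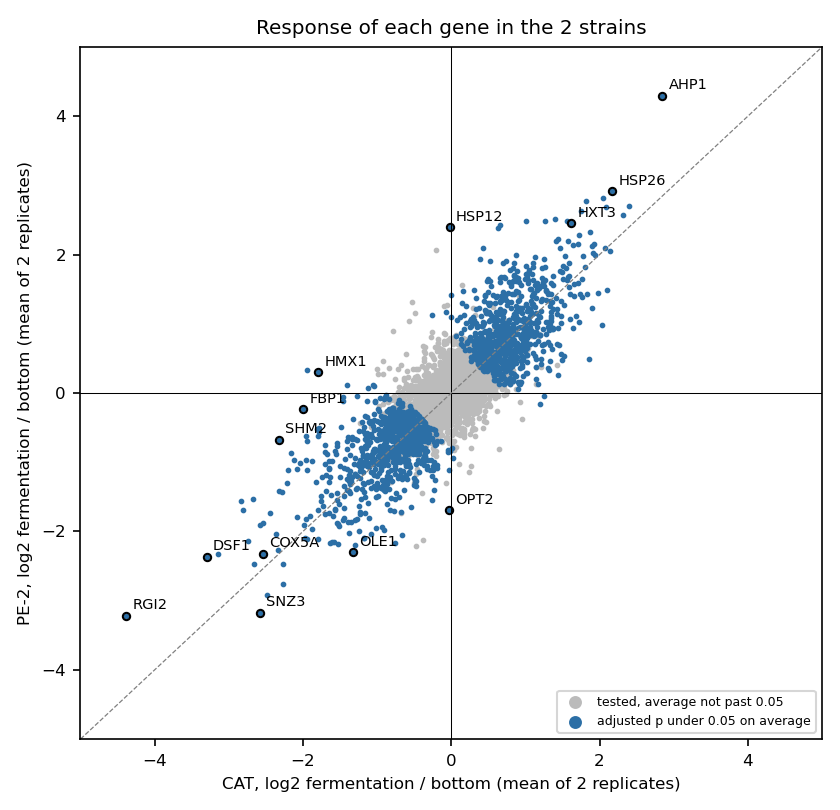
Mean log2 change (fermentation over bottom) of each of the 5384 genes tested in CAT (x axis) and in PE-2 (y axis), with genes past an adjusted p of 0.05 on average over the strains in blue, the others in grey, and the dashed line at equal change. AHP1 lies at 2.85 and 4.30 and RGI2 at -4.38 and -3.22, while HSP12 lies at -0.02 in CAT, where its probe was dim in fermentation, and 2.40 in PE-2. Both axes are after loess within each array, and so are relative to genes of similar intensity.

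The average over both strains gave each gene's mean change, which can pass where 1 strain alone passed, as for FBP1, fructose-1,6-bisphosphatase (-1.12, with -0.23 in PE-2). AHP1 (3.57), HSP26 (2.55), ADH1 (2.43) and PDC1, pyruvate decarboxylase (1.89), rose, and RGI2 (-3.80), SNZ3 (-2.88) and COX5A (-2.43) fell. On average 1589 genes passed, 777 higher and 812 lower, from 4 replicates. Of the genes called in each strain, 126 rose in both, where 12.1 would be shared by independent lists of these sizes, and 163 fell in both, where 16.0 would be. The strains' tests of a gene share its SE, so genes of small SE are called more readily in both. The lists are thus not independent, and some of this excess could come from the shared SE. limma called 0 genes in opposite directions in the strains. Of the CAT calls, 211 of 213 higher genes and 272 of 280 lower genes had the same sign in PE-2. The strains' changes correlated across genes at r = 0.815 (Spearman 0.804). Median centring moved the split of average calls to 470 higher and 1212 lower, the processed signals to 756 and 1202, and centring on added control transcripts to 1 and 1088. Without CAT replicate 1 there were 257 average calls, without CAT replicate 2 there were 855 and without PE-2 replicate 1 there were 903.

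Among the fixed genes, PDC1 rose by 1.64 in CAT and 2.14 in PE-2 (SE 0.18; adjusted p = 0.014 and 0.0082). HXT3 rose by 1.62 in CAT (SE 0.16; adjusted p = 0.010). PCK1, phosphoenolpyruvate carboxykinase of gluconeogenesis, fell by 1.58 and 2.16 (SE 0.20; adjusted p = 0.018 and 0.0082). SUC2, invertase, had changes of -0.04 and -0.22 (SE 0.17; adjusted p = 0.88 and 0.46), and HXT1, a low-affinity glucose transporter, of 0.29 and 0.80 (SE 0.23; adjusted p = 0.43 and 0.082). ADH2, the ethanol-oxidising alcohol dehydrogenase, had 0.30 in CAT (adjusted p = 0.36) and rose by 1.11 in PE-2 (adjusted p = 0.031). Its probe shares at least 20 bases with that of ADH1. The log2 signal of HXT1 was 6.1 at the bottom in each strain, and 6.4 in CAT and 6.9 in PE-2 in fermentation. That of ADH2 was 6.1 and 6.4 in CAT and 6.2 and 7.3 in PE-2, at the bottom and in fermentation. At such low signals the offset added in background correction draws ratios towards 0. The small changes of HXT1 and ADH2 thus do not show that these genes were unchanged. SNZ1 fell by 1.94 in CAT (adjusted p = 0.0092) and had -0.69 in PE-2 (adjusted p = 0.069).

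**Figure D2:**
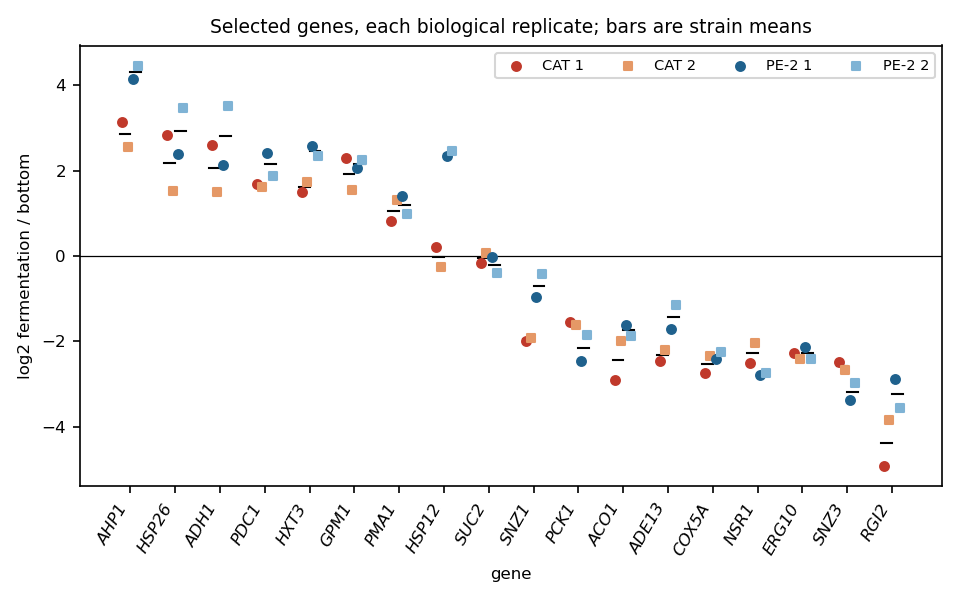
Log2 change (fermentation over bottom, y axis) of 18 genes (x axis) in each biological replicate, as points, with bars at the strain means. AHP1 was above 0 and RGI2 below 0 in all 4 replicates, whereas HSP12 had 0.22 and -0.26 in the CAT replicates and 2.34 and 2.45 in the PE-2 replicates.

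Gene lists described the central carbon and energy genes next. Glycolysis genes rose as a list, with medians of 0.71 in CAT and 0.65 in PE-2. Of its 17 tested members, 4 rose and 1 fell in CAT and 3 rose in PE-2 (8 higher and 1 lower, and 6 higher and 1 lower, adjusted over the list alone). The list had adjusted p = 5.9e-04 and 0.0039 by camera, and adjusted p = 0.49 and 0.58 with an estimated correlation. GPM1, phosphoglycerate mutase, rose by 1.92 and 2.15 (SE 0.22) and TDH1, glyceraldehyde-3-phosphate dehydrogenase, by 1.34 and 1.43 (SE 0.28). TPI1, triosephosphate isomerase, rose by 1.48 in CAT (SE 0.31) and had 1.33 in PE-2. TDH genes may cross-hybridise, and spots of TDH1 were saturated on 3 arrays and of GPM1 on 1, so their values are uncertain. The dye effect, which stays in the unswapped CAT replicate 1, was 0.69 for TDH1, 0.50 for GPM1 and 0.07 for TPI1 (log2 red over green). The CAT rises of TDH1 and GPM1 are thus likely too high. Without PE-2 replicate 1 the list missed the threshold in PE-2 (adjusted p = 0.12).

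Tricarboxylic acid (TCA) cycle genes fell, with medians of -0.91 in CAT and -0.94 in PE-2. Of 20 tested members, 8 fell in CAT, and 10 fell and 1 rose in PE-2 (15 lower, and 13 lower and 1 higher, adjusted over the list alone). With camera the list had adjusted p = 5.1e-07 and 9.1e-07, and adjusted p = 0.49 and 0.58 with an estimated correlation. ACO1, aconitase, fell by 2.44 and 1.73 (SE 0.25), SDH2, of succinate dehydrogenase, by 2.29 and 1.42 (SE 0.30), and PYC1, pyruvate carboxylase, by 1.80 and 1.69 (SE 0.20). Nuclear genes of the respiratory chain and ATP synthase fell too, with medians of -1.05 and -0.60. In replicates 1 and 2 the medians were -1.25 and -0.62 in CAT, and -0.60 and -0.46 in PE-2. Of 36 members, 14 fell and 1 rose in CAT and 10 fell and 1 rose in PE-2 (17 lower and 2 higher, and 18 lower and 1 higher, adjusted over the list alone). By camera, adjusted p = 1.2e-06 and 5.9e-05, and adjusted p = 0.49 and 0.58 with an estimated correlation. NDE1, the external NADH dehydrogenase, fell by 2.09 and 1.78 (SE 0.15), RIP1, the Rieske protein, by 1.91 and 1.77 (SE 0.22), and ATP3, of ATP synthase, by 1.73 and 1.64 (SE 0.29).

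Gluconeogenesis and glyoxylate cycle genes fell as a list in CAT (median -0.36), where 7 of 22 members fell (7 lower and 1 higher adjusted over the list alone). In PE-2 (median -0.09) 6 fell and 3 rose (7 lower and 3 higher adjusted over the list alone). As a list it had adjusted p = 0.016 and 0.13 by camera, and adjusted p = 0.49 and 0.58 with an estimated correlation. JEN1, a lactate transporter, fell by 2.21 and 1.31 (SE 0.18), CIT2, peroxisomal citrate synthase, by 1.30 and 1.84 (SE 0.20), and MDH3, peroxisomal malate dehydrogenase, by 1.27 and 1.38 (SE 0.19). Beta-oxidation and peroxisome genes fell in CAT (median -0.27), with 3 of 18 members lower (4 adjusted over the list alone), among them CTA1, peroxisomal catalase, by 1.28 and POT1, thiolase, by 1.13. In PE-2 (median -0.09) 0 of 18 passed in limma, 0 adjusted over the list alone. Tested together by camera, they had adjusted p = 0.043 and 0.60, and adjusted p = 0.51 and 0.74 with an estimated correlation; the CAT call held in 9 of 14 alternatives and was lost without either CAT replicate (adjusted p = 0.079 without replicate 1 and 0.056 without replicate 2).

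Ribosome biogenesis genes fell, with medians of -0.40 and -0.30, and 10 of 116 members fell in CAT and 12 in PE-2 (18 and 1 adjusted over the list alone). In replicates 1 and 2 the medians were -0.44 and -0.37 in CAT, and -0.51 and -0.16 in PE-2. The list had adjusted p = 1.1e-09 and 6.4e-07 by camera, and adjusted p = 0.53 and 0.69 with an estimated correlation. NSR1 fell by 2.27 in CAT, SAS10, a processome component, by 1.63 and 1.47 (SE 0.25), and NSA2 by 1.45 and 1.48 (SE 0.27). Translation factors fell, with medians of -0.36 and -0.35. Of 40 members, 3 fell and 1 rose in CAT and 8 fell and 1 rose in PE-2 (9 lower and 1 higher, and 12 lower and 1 higher, adjusted over the list alone). With camera the list had adjusted p = 0.0031 and 2.6e-04, and adjusted p = 0.53 and 0.58 with an estimated correlation. YEF3, elongation factor 3, fell by 1.53 and 2.18 (SE 0.17), while ANB1, the hypoxic form of eIF5A, rose by 1.76 and 1.39 (SE 0.17). The list's CAT call was lost without CAT replicate 1 (adjusted p = 0.075).

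Cytosolic ribosomal protein genes rose as a list in CAT (median 0.20), where 8 of 135 rose and 2 fell (5 and 2 adjusted over the list alone). In PE-2 (median -0.10) 1 rose and 14 fell (1 and 14 adjusted over the list alone). By camera, adjusted p = 0.0071 and 0.061, and adjusted p = 0.64 and 0.74 with an estimated correlation. The CAT medians were 0.01 in replicate 1 and 0.33 in replicate 2, and without CAT replicate 2 the list missed the threshold (adjusted p = 0.71). Against the list's direction in CAT, RPS2 fell by 1.30 and 2.20 (SE 0.21) and RPS27A by 1.50 and 1.22 (SE 0.18), while RPL10 and RPS3 had -1.01 and -1.10 in CAT and fell by 1.94 and 1.81 in PE-2 (SE 0.29 and 0.34). Mitochondrial ribosomal protein genes fell in CAT (median -0.15), with 5 of 71 lower (4 adjusted over the list alone), and had a median of -0.08 in PE-2, with 5 lower and 3 higher (5 and 3 adjusted over the list alone). As a list it had adjusted p = 0.029 and 0.22 by camera, and adjusted p = 0.49 and 0.62 with an estimated correlation. RSM28 fell by 1.76 and 1.49 (SE 0.23) and MRPS12 by 1.08 and 1.13 (SE 0.14); the list's CAT call held in 9 of 14 alternatives and was lost without CAT replicate 1 (adjusted p = 0.12).

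Purine synthesis genes fell, with medians of -0.96 in CAT and -0.32 in PE-2, and 11 of 22 members fell in CAT and 7 in PE-2 (15 lower and 1 higher, and 10 lower, adjusted over the list alone). It had adjusted p = 3.0e-07 and 0.0035 by camera, and adjusted p = 0.49 and 0.58 with an estimated correlation. ADE13, adenylosuccinate lyase, fell by 2.32 and 1.42 (SE 0.19), FCY2, a purine-cytosine permease, by 1.70 and 1.75 (SE 0.16), and SHM2, cytosolic serine hydroxymethyltransferase, by 2.33 and 0.67 (SE 0.15). Thiamine and vitamin B6 genes fell, with medians of -0.53 and -0.69, and 8 of 24 fell in each strain (9 and 14 adjusted over the list alone). Tested together by camera, they had adjusted p = 1.2e-04 and 6.4e-07, and adjusted p = 0.51 and 0.58 with an estimated correlation. THI5, of thiamine precursor synthesis, fell by 2.20 and 1.12 (SE 0.15); its probe shares at least 20 bases with that of THI12, which fell by 2.08 and 1.09.

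Ergosterol synthesis genes fell as a list, with medians of -0.33 and -0.25, and with 6 of 31 lower in CAT and 4 lower and 1 higher in PE-2 (7 lower, and 5 lower and 1 higher, adjusted over the list alone). In replicates 1 and 2 the medians were -0.47 and -0.15 in CAT, and -0.50 and -0.16 in PE-2. The list had adjusted p = 0.0067 and 0.039 by camera, and adjusted p = 0.49 and 0.58 with an estimated correlation. IDI1, isopentenyl diphosphate isomerase, fell by 1.54 and 1.87 (SE 0.18) and ERG13, HMG-CoA synthase, by 1.96 and 0.96 (SE 0.17). The PE-2 call held in 7 of 14 alternatives; it was lost without PE-2 replicate 2 (adjusted p = 0.052), with processed signals, the series table, scale normalization or Cy5 arrays alone, and with fry or an estimated correlation. Iron, zinc and copper uptake genes fell in CAT (median -0.24), with 6 of 31 lower and 1 higher (11 and 1 adjusted over the list alone). In PE-2 (median -0.16) 5 fell and 3 rose (5 and 3 adjusted over the list alone). With camera the list had adjusted p = 0.013 and 0.17, and adjusted p = 0.49 and 0.67 with an estimated correlation. IZH2 and IZH1, of zinc homeostasis, fell by 1.94 and 1.65 in CAT and by 2.12 and 1.74 in PE-2 (SE 0.41 and 0.29). CUP1-1, metallothionein, had 0.65 in CAT and rose by 2.43 in PE-2 (SE 0.23), with a probe identical to that of CUP1-2. Without CAT replicate 1 the metal uptake list missed the threshold in CAT (adjusted p = 0.060).

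Chaperone genes rose, with medians of 0.37 and 0.79, and 4 of 30 rose in CAT and 14 in PE-2 (7 and 20 adjusted over the list alone). By camera, adjusted p = 0.029 and 6.4e-07, and adjusted p = 0.53 and 0.58 with an estimated correlation. SSE2, an Hsp110 chaperone, rose by 1.50 and 1.84 (SE 0.19); SSE1 had 0.85 in CAT and rose by 1.88 in PE-2 (SE 0.19). Without CAT replicate 1 the chaperone list missed the threshold in CAT (adjusted p = 0.19). General stress genes rose as a list in PE-2 (median 0.46, with 0.78 and 0.23 in replicates 1 and 2), where 9 of 39 rose (11 higher and 1 lower adjusted over the list alone). In CAT (median 0.27) 6 rose and 2 fell (9 and 3 adjusted over the list alone). As a list it had adjusted p = 0.054 in CAT and 3.7e-05 in PE-2 by camera, and adjusted p = 0.76 and 0.67 with an estimated correlation. TFS1, a carboxypeptidase Y inhibitor, had 1.53 in CAT and rose by 1.98 in PE-2 (SE 0.41), and SPI1, a cell wall protein, had 0.74 and rose by 1.91 (SE 0.27).

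Cell wall genes rose, with medians of 0.49 and 0.37, and 8 of 39 rose in CAT, and 8 rose and 4 fell in PE-2 (12 higher and 1 lower, and 13 higher and 4 lower, adjusted over the list alone). Tested together by camera, they had adjusted p = 5.0e-05 and 0.0043, and adjusted p = 0.53 and 0.69 with an estimated correlation. CIS3, a wall glycoprotein, rose by 1.83 and 1.44 (SE 0.14), CWP2, a mannoprotein, by 1.46 and 1.76 (SE 0.21), and SLT2, the cell integrity kinase, by 1.26 and 1.82 (SE 0.21). The PE-2 call of the wall list was lost without PE-2 replicate 1 (adjusted p = 0.14). Proton pump genes rose, with medians of 0.45 and 0.35, and 5 of 18 rose in CAT, and 3 rose and 1 fell in PE-2 (the same counts adjusted over the list alone). The list had adjusted p = 0.0013 and 0.029 by camera, and adjusted p = 0.49 and 0.58 with an estimated correlation. PMA1, the plasma membrane proton ATPase, rose by 1.06 and 1.19 (SE 0.20) and VMA10, of the vacuolar ATPase, by 1.24 and 1.61 (SE 0.15); the PE-2 call held in 9 of 14 alternatives and was lost without PE-2 replicate 2 (adjusted p = 0.13).

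Smaller shifts were called in other lists. Anaerobic cell wall genes rose as a list in PE-2 (median 0.17), a direction that turned under median centring, with 1 of 29 higher in each strain (1 in CAT and 0 in PE-2 adjusted over the list alone). It had adjusted p = 0.084 and 0.045 by camera, and adjusted p = 0.53 and 0.58 with an estimated correlation. The call held in 4 of 14 alternatives, and was lost without PE-2 replicate 1 (adjusted p = 0.56) and without either CAT replicate (adjusted p = 0.051). TIR3 rose by 1.31 and 1.03 (SE 0.22). Nitrogen catabolite repression genes rose in PE-2 (median 0.21; 0.13 in CAT), with 10 of 38 higher and 2 lower (12 and 6 adjusted over the list alone), and 5 higher and 2 lower in CAT (6 and 5). With camera the list had adjusted p = 0.22 in CAT and 0.048 in PE-2, and adjusted p = 0.76 and 0.70 with an estimated correlation. The medians were 0.55 and 0.05 in PE-2 replicates 1 and 2, and the call held in 5 of 14 alternatives; it was lost without PE-2 replicate 1 (adjusted p = 0.56) and without either CAT replicate (adjusted p = 0.051). DAL80, a GATA repressor, rose by 1.71 and 1.59 (SE 0.30), and GDH2, NAD-dependent glutamate dehydrogenase, fell by 1.46 and 1.84 (SE 0.21).

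Proteasome genes fell in PE-2 (median -0.45), where 7 of 34 fell (9 adjusted over the list alone), and had a median of 0.05 in CAT, with 1 lower (0 adjusted over the list alone). By camera, adjusted p = 0.80 in CAT and 0.0024 in PE-2, and adjusted p = 0.83 and 0.58 with an estimated correlation. The PE-2 call was lost with the processed signals and with the series table. RPN6, a lid subunit, fell by 0.94 and 1.11 (SE 0.19). Cell cycle and DNA replication genes rose as a list in CAT (median 0.18; 0.10 in PE-2), with 1 of 27 higher in CAT and 0 in PE-2 in limma (0 and 0 adjusted over the list alone). As a list it had adjusted p = 0.0060 and 0.45 by camera, and adjusted p = 0.49 and 0.70 with an estimated correlation. The CAT call was also lost with fry and with the strict filter on dim probes. RNR4, of ribonucleotide reductase, rose by 0.75 in CAT (SE 0.15).

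Mitochondrially encoded genes, a sign of RNA or labelling quality, fell as a list in CAT (median -0.76), where 3 of 7 fell (3 adjusted over the list alone), and had a median of 0.34 in PE-2, with 0 called in limma (0 adjusted over the list alone). Tested together by camera, they had adjusted p = 0.029 and 0.43, and adjusted p = 0.54 and 0.74 with an estimated correlation. ATP8 fell by 1.95 (SE 0.24) and OLI1 by 1.16 (SE 0.22) in CAT; spots of OLI1 were saturated on 3 arrays, so its value is uncertain. The medians by replicate were -1.21 and 0.13 in CAT and 0.32 and 0.38 in PE-2, so the low CAT median came with CAT replicate 1, the array without a swap, although ATP8, OLI1 and VAR1 were below 0 in both CAT replicates (adjusted p = 0.46 for the list without it; the call held in 8 of 13 alternatives). Lists for other cell states were not called: mating and haploid-specific genes had medians of 0.09 and -0.03 (adjusted p = 0.44 and 0.66 by camera, and adjusted p = 0.75 and 0.78 with an estimated correlation), with 0 of 18 called in CAT in limma and 1 higher in PE-2 (0 and 1 adjusted over the list alone). Meiosis and sporulation genes had medians of 0.13 and 0.09 (adjusted p = 0.054 and 0.15 by camera, and adjusted p = 0.49 and 0.58 with an estimated correlation), with 1 of 20 higher in CAT and 2 in PE-2 (1 and 2 adjusted over the list alone). In all, camera called 18 of 38 lists in CAT and 15 in PE-2, and with an estimated correlation it called 0 in either strain, with lowest adjusted p = 0.49 and 0.58. With 2 residual degrees of freedom the latter form had little power, so its 0 calls do not decide whether lists changed. The preset form takes list members as nearly independent, so its calls do not decide it either.

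**Figure D3:**
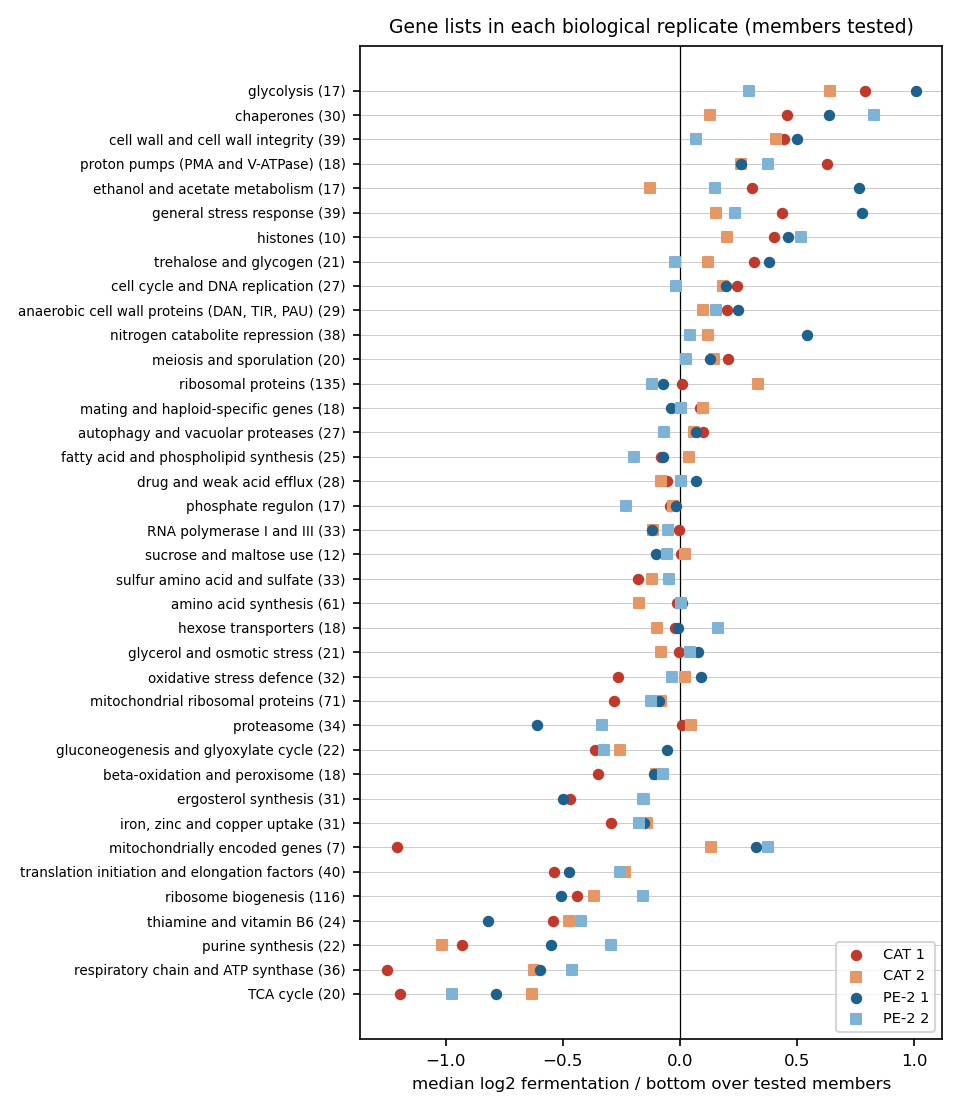
Median log2 change (fermentation over bottom, x axis) over the tested members of each of 38 gene lists, as points for the 4 biological replicates, with the number of members in parentheses. The TCA cycle and purine synthesis lists were below 0 in all 4 replicates, and the mitochondrially encoded list was at -1.21 in CAT replicate 1 and at 0.13 to 0.38 in the others.

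The strain difference asked whether the response to fermentation differed between CAT and PE-2. HSP12, a membrane-stabilising heat shock protein, rose 5.27-fold in PE-2 (2.40 ± 0.18, SE, n = 2), and in CAT, where it was not well above background in fermentation, it had 0.22 and -0.26 in the 2 replicates. HMX1, heme oxygenase, and FBP1 fell by 1.80 and 2.00 in CAT and had 0.30 and -0.23 in PE-2 (SE 0.16). DDR2, a stress gene, had 0.42 in CAT and rose by 2.10 in PE-2 (SE 0.15), and OPT2, an oligopeptide transporter, had -0.03 and fell by 1.69 (SE 0.18). These values compare responses, not levels, and the strains were on separate arrays. The log2 signal of DDR2 was 10.1 at the bottom and 10.6 in fermentation in CAT, against 6.3 and 8.4 in PE-2. That of HSP12 was 6.3 at both stages in CAT, and 5.9 at the bottom and 8.3 in fermentation in PE-2. A signal as low as 5.9 lies near the offset added in background correction, so the PE-2 fold of HSP12 is uncertain. None of these differences passed: limma called 0 of 5384 genes (327 at an unadjusted p under 0.05), with a lowest adjusted p of 0.31. The 10 genes named by lowest p thus missed the threshold (adjusted p = 0.31 to 0.48).

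CAT minus PE-2 was 1.67 for OPT2, 1.28 for ARO3 (DAHP synthase), 1.36 for NCW1 (a cell wall protein), 1.45 for SSU1 (the sulfite pump) and 1.09 for VMA6 (of the vacuolar ATPase). It was -2.42 for HSP12 (inexact, as within slide 2, since its probe was not well above background in fermentation in CAT), -2.10 for HMX1, -1.76 for FBP1, -1.67 for DDR2 and -1.65 for RSC30, whose probe is identical to that of YHR054C. Within slide 2, which held CAT replicate 2 and PE-2 replicate 2, these were 1.51, 1.31, 1.53, 1.08 and 1.11, and -2.72, -2.20, -1.60, -1.62 and -1.60. The rule for naming these genes fixed the signs within slide 2, so the slide 2 values are no separate check. A fit to the 7 arrays with a dye term called 4 genes for the difference, all with a lower change in CAT. They were HSP12 and HMX1 (adjusted p = 0.016) and FBP1 and SHM2 (adjusted p = 0.048). Swapped arrays of a replicate add to the error degrees of freedom of that fit, so its p-values may be too small. Over all alternatives the adjusted p of HSP12, HMX1 and FBP1 reached 1. With slide as a random block over the 7 arrays, which counts swapped arrays as separate replicates, 2430 genes passed.

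As lists, 11 of 38 differed between the strains by camera, and 0 with an estimated correlation (lowest adjusted p = 0.53, with little power from 2 residual degrees of freedom). With fry, 0 were called (lowest adjusted p = 0.095, and 0.51 for ribosomal proteins). The preset form of camera takes members as nearly independent, so its p-values may be too small. Slide 2 held CAT replicate 2 and PE-2 replicate 2, which also entered each difference, so its values are no separate check. Ribosomal protein and proteasome genes had higher changes in CAT than in PE-2, with median differences of 0.36 and 0.38 (0.50 and 0.34 within slide 2, adjusted p = 5.1e-15 and 5.7e-08 by camera, and adjusted p = 0.60 and 0.53 with an estimated correlation). Chaperones and purine synthesis had lower changes in CAT, by medians of -0.69 and -0.42 (-0.67 and -0.51 within slide 2, adjusted p = 2.1e-07 and 9.3e-07 by camera, and adjusted p = 0.60 and 0.53 with an estimated correlation). Under median centring the direction for chaperones turned and the call for purine synthesis was lost. Hexose transporters, of which 5 of 18 fell and 1 rose in CAT and 3 fell and 2 rose in PE-2 (5 and 2, and 3 and 4, adjusted over the list alone), differed by -0.41 (-0.71 within slide 2; adjusted p = 2.9e-05 by camera, and adjusted p = 0.60 with an estimated correlation); without PE-2 replicate 2 they missed the threshold (adjusted p = 0.062). Single members passed the difference test in 0 cases among the 11 lists. Adjusted over the list alone, some members had a lower change in CAT. These were 9 of 22 purine, 3 of 39 general stress, 3 of 18 beta-oxidation, 2 of 7 mitochondrially encoded and 1 of 18 hexose transporter genes, and 0 in the other 6 lists.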

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

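The tests of dye bias on the control transcripts and of the amount of yeast messenger RNA were chosen after the results were seen.

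The 10 added control transcripts, which the comparisons did not use, gave a signal of their own. Their ratio of fermentation to bottom, over that of the yeast genes, was 1.619 in CAT replicate 1, -0.407 in CAT replicate 2, 1.255 in PE-2 replicate 1 and 2.467 in PE-2 replicate 2 (log2). CAT replicate 1 had no swap, so its value was the 2.10 of its array less the mean dye offset of the swapped replicates. Those offsets were 0.64 in CAT replicate 2 and 0.12 and 0.69 in PE-2 replicates 1 and 2. The value and fold of CAT replicate 1 thus rest on a borrowed dye correction. Set against these transcripts, yeast genes were 3.07-fold, 2.39-fold and 5.53-fold lower in fermentation in 3 replicates. In CAT replicate 2 they were higher in fermentation (control transcripts at 0.754 times the yeast genes). Dye bias is argued against in PE-2, where the offset that followed the sample was at least 3.599 times the one that followed the dye. In CAT that ratio was 0.64 in the 1 swapped pair, and replicate 1 had no swap, so dye bias there cannot be told apart from a sample effect. Less yeast messenger RNA per unit of total RNA in fermentation may be a further explanation (3 of 4 replicates had a positive offset), and so may unequal amounts of added transcripts; the labels give no amounts.

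The test of strain difference called 11 gene lists, and each difference is CAT minus PE-2 in median log2 change. The replicates on slide 2 also entered each difference, so the slide 2 values are no separate check. Ribosomal proteins differed by 0.363 (0.50 within slide 2), the proteasome by 0.377 (0.34), and cell cycle and DNA replication by 0.18 (0.25; its direction turned under median centring). Hexose transporters differed by -0.408 (-0.71 within slide 2) and chaperones by -0.686 (-0.67, turned under median centring). Purine synthesis differed by -0.423 (-0.51) and general stress genes by -0.229 (-0.20), and both calls were lost under median centring. Sulfur amino acid genes differed by -0.294 (-0.17 within slide 2) and beta-oxidation genes by -0.152 (-0.01). The respiratory chain differed by -0.135, but by 0.02 within slide 2, and turned under median centring. Calls were lost without CAT replicate 1 for the respiratory chain (adjusted p = 0.97), beta-oxidation (0.19) and the cell cycle (0.086), and without CAT replicate 2 for general stress (0.24). They were lost without PE-2 replicate 1 for general stress (0.82), the respiratory chain (0.19), beta-oxidation (0.078) and sulfur amino acids (0.078), and without PE-2 replicate 2 for beta-oxidation (0.11), the cell cycle (0.11) and hexose transporters (0.062). Of 14 alternatives, the call held in 4 for the respiratory chain, 6 for beta-oxidation, 6 for the cell cycle, 8 for general stress and 9 for sulfur amino acids. With an estimated correlation the lowest adjusted p of the 11 was 0.53.

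Mitochondrially encoded genes differed by -0.843 between the strains and by -0.25 within slide 2, which lacks CAT replicate 1. The difference was called in 11 of 13 alternatives, without CAT replicate 1 among them, and was lost with fry and with an estimated correlation. The list median was -1.21 in CAT replicate 1 and 0.13 in CAT replicate 2, although the 3 members called in CAT were below 0 in both: ATP8 (-2.41 and -1.49), OLI1 (-1.55 and -0.77) and VAR1 (-0.72 and -1.03). For the list median, a dye effect on the array without a swap is argued against, since the median red-over-green effect of these genes was 0.028 in the 3 swapped pairs. COB is an exception, with a dye effect of -0.47 (-0.88 to -0.32), the same sign as its -1.83 in CAT replicate 1. The effects of the other members were -0.08 to 0.22, and that of OLI1 varied between pairs (-0.51 to 0.57). Slide 3 held CAT replicate 1 alone, so slide and replicate cannot be told apart, and a strain difference in these genes stays open.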

How the results depend on the processing

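The crossed pairing of replicates and centring on control transcripts were chosen after the results were seen; the other alternatives were planned. Against 493 genes in CAT, 613 in PE-2, 1589 on average and 0 for the strain difference (limma; 327 at an unadjusted p under 0.05), scale normalization between arrays gave 0 in CAT (1601 at an unadjusted p under 0.05; lowest adjusted p 0.052). No filter gave 163 in CAT and 271 in PE-2, and the strict filter 1058 on average (631 higher and 427 lower). PE-2 had 1301 calls with processed signals, 1307 with the series table, 1234 with median centring and 302 fitted alone. A dye term with replicate as a random effect gave 998, 1110 and, for the difference, 4. Swapped arrays add to the error degrees of freedom of that fit, so its counts may be too high. An adjusted p under 0.01 left 45, 81 and 468, and a 2-fold limit 457 on average. Leaving out 1 replicate, where a lone replicate is assumed to vary like the other strain's, gave 0 to 626 in CAT, 46 to 307 in PE-2, 257 to 1333 on average and 0 to 0 for the difference (235 to 403 at an unadjusted p under 0.05). The lowest count in CAT came without either CAT replicate, the lowest on average without CAT replicate 1, and the lowest in PE-2 without PE-2 replicate 1. The correlation of the strains was then 0.704 to 0.798, and lists called were 12 to 19 in CAT, 13 to 15 in PE-2 and 9 to 13 for the difference.

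Replicate numbers do not pair the strains: same-numbered replicates deviated from their strain means with a correlation of -0.46. Replicate number as a block gave 0 in CAT (1263 at an unadjusted p under 0.05 in limma), 0 in PE-2 (1239), 801 on average and 0 for the difference (186). The crossed pairing as a block gave 1852, 1698, 2533 and 95. Slide as a random block over 7 arrays (estimated correlation 0.848), which counts swapped arrays of the same RNAs as separate, gave 1599, 1511 and, for the difference, 2430, and a correlation of the strains of 0.653. With an estimated inter-gene correlation, which had little power here, 0 lists were called in CAT, 0 in PE-2 and 0 for the difference, and fry called 1, 0 and 0.

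Centring on control transcripts shifts all genes of a replicate by 1 constant, so any small rise turns by construction and this says nothing about single genes. It gave 3 genes in CAT, and 24 named genes then had averages below 0: HXT1 -0.69, ADH2 -0.53, HSP12 -0.046, PMA1 -0.11, PDC5 -0.023, TIR3 -0.063, TIR1 -0.32, DAN1 -0.47, PEX21 -0.70, RNR4 -0.69, RNR2 -0.75, POL2 -0.82, MCM6 -0.86, HHF1 -0.033, HTA2 -0.16, MATALPHA2 -0.16, STE18 -0.77, MATALPHA1 -0.90, OSW2 -0.19, SPR28 -0.38, DMC1 -0.51, SPS100 -0.63, VMA1 -0.056 and VMA4 -0.45. It left another 61 values short of the threshold. Without CAT replicate 1, COB turned from -0.28 to 0.25 on average, and 71 other values fell short of the threshold. The brightest-probe alternative was not run, since each gene had 1 probe.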

Other observations

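The enrichment of annotation terms and the tests of slide, exchanged strain labels and state before feeding were chosen after the results were seen. Of the 15 annotated genes of the tricarboxylic acid cycle, 12 fell on average over both strains, where 2.43 would be drawn by chance (adjusted p = 3.58e-05, from draws that treat genes as independent; the matching gene list had adjusted p = 0.45 on average with an estimated correlation). Glutamate biosynthesis had 6 of 6 lower (0.97 expected) and vitamin B6 metabolism 5 of 5 (0.808 expected), with SNZ1, SNZ2 and SNZ3 among the latter. ATP synthesis coupled proton transport, the ATP synthase genes, had 11 of 19 lower (3.07 expected). Protein folding had 16 of 34 higher (4.52 expected) and the cell wall 8 of 12 (1.62 expected). With an estimated correlation the matching respiratory chain, chaperone, cell wall, and thiamine and vitamin B6 lists had adjusted p = 0.45, 0.45, 0.57 and 0.45 on average. In all, 12 of 448 terms passed.

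Lists called in neither strain held single genes that changed. ACS2, acetyl-CoA synthetase, fell by 1.51 in CAT and 1.60 in PE-2 (SE 0.25), and PDC5, pyruvate decarboxylase, rose by 1.34 and 1.08 (SE 0.19). FAS1, fatty acid synthase, had -1.61 in CAT and fell by 2.15 in PE-2 (SE 0.41), and ITR1, a myo-inositol transporter, fell by 1.27 in CAT (SE 0.20) and also passed, lower, in PE-2 (adjusted p = 0.027). CYS3, cystathionine gamma-lyase, rose by 1.44 and 2.23 (SE 0.24), while MET6, methionine synthase, fell by 1.81 in CAT and had -0.51 in PE-2 (SE 0.23). TPO2, a polyamine exporter, rose by 1.65 and 1.41 (SE 0.15), and QDR2, a multidrug transporter, fell by 1.82 and 1.29 (SE 0.22). HHF2, a histone H4 gene, rose by 1.74 and 1.43 (SE 0.25). The 16 lists called in neither strain had medians of -0.13 to 0.58.

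CAT replicate 1 correlated with PE-2 replicate 2 at 0.765 and CAT replicate 2 with PE-2 replicate 1 at 0.778, above the 0.735 and 0.685 within strains. Exchanged strain labels are argued against: 143 genes separated the labelled strains by over 1 log2 unit of intensity and 0 the crossed pairs, a ratio of 0. Dim spots are argued against, since the correlation of deviations among the brightest genes was -0.595. A slide or scan batch stays open: the replicates sharing slide 2 deviated with a correlation of -0.46, but this is the same pattern seen from the other pair, and slides 1 and 3 held 1 replicate each. A different state of the cells before feeding may be a candidate explanation: the crossed contrast had 0.964 times the spread in the bottom channel that it had in fermentation, which does not separate the 2 stages.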
